A study of Mus musculus with 12 samples.

How the data were processed

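Total RNA from peritoneal exudate cells, the mixed cells flushed from the abdominal cavity with cold saline, was measured on 12 single-colour Agilent mouse arrays. Per the labels, the cells came from female mice of 8 weeks, either wild type or lacking Ifnar2, the gene of a receptor subunit for type I interferons, and were lysed 3 hours after an injection into the peritoneal cavity. The injection held either interferon beta (IFN-β, stated as 10000 IU/ml with no volume) or phosphate-buffered saline (PBS), which made 4 groups of 3 arrays. Per the series' design text, different mice were used for each sample in independent experiments, so the spread within a group includes differences between animals. The strain is given as 129S2/SvPas*BALB/c in the labels.

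Per the labels' protocols, RNA was purified on RNeasy columns with DNase digestion, and Cy3-labelled complementary RNA was made from 0.2 µg of RNA by a low-input amplification kit. Per the file headers, the arrays were quantified with Agilent Feature Extraction 9.5.3.1, which subtracted a spatially fitted background and removed a multiplicative trend within each array. The deposited processed signal is therefore an intensity on a linear scale that was not normalized between arrays. The deposited mean signal and local background of each spot are intensities before that correction, and other deposited columns mark spots that were well above background, saturated or outliers. The deposited value table of the whole series was compared with the scanner files: 0 of 45018 values differed on any array by more than rounding, so its values are the linear processed signals, neither centred nor turned, with column medians from 50.7 to 77.6. An analysis of that table would repeat the analysis of the scanner files and was not run on its own; log2 of the same values with no scaling between arrays was run in its place.

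Each array held 43379 spots that were not controls, for 41174 probes. Between 59.4% and 71.6% of these spots were well above background per array, and between 1 and 29 were saturated. The Ifnar2-/- arrays numbered 2 and 3, which alone lay on slide 3, had 59.4% to 62.5% and 23 to 29. The other arrays had 65.2% to 71.6% and 1 to 4. The 75th percentile of the processed signal lay between 659 and 968. Spots marked as non-uniform or as population outliers were left out, 84 to 167 per array, and spots of a probe were averaged. The main values were log2 of the processed signal minus the array's 75th percentile of it. In these values the lowest signal among probes well above background was -5.46 to -5.02 on the slide 3 arrays and -6.67 to -6.07 on the others. Genes near background therefore had unlike limits of detection on slide 3. A probe was kept when it was well above background on all arrays of at least 1 group and had a value on at least 6 arrays, which left 27718 probes. A gene was represented by its probe with the highest mean signal, which left 18276 genes. The number of arrays limits the precision of every comparison.

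Probes were named through a table of RefSeq accessions and symbols for the mouse assembly GRCm38.p6, used for names and for gene order only. By accession 22951 probes matched, 6659 matched by symbol and 3109 by an older symbol, and 8455 kept the name in the files. Of 6355 genes with several kept probes, probes passed the test in opposite directions for 95 genes in the wild-type comparison, 0 in the knockout comparison, 11 in the comparison of responses and 13 in the PBS comparison. Among genes of the lists these were Ripk1 and Itsn1 in wild type, Itsn1 in the comparison of responses, and Ifnar2 and Tor3a after PBS. Chromosome positions are those the array files give, and the genome build behind them is not given in the sources used here.

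All 12 arrays entered a single limma 3.58.1 fit with 4 group means in R 4.3.3, with files read by version 1.17.8 of data.table. The moderated test of limma had 8 residual and 2.38 prior degrees of freedom. The comparisons were IFN-β against PBS in wild type, IFN-β against PBS in Ifnar2-/-, the difference between these responses, and Ifnar2-/- against wild type after PBS. All tests were two-sided, p values were adjusted by the Benjamini-Hochberg method within each comparison over the 18276 genes, and an adjusted p under 0.05 was the threshold. Errors of log2 fold changes are standard errors (SE) from the fit, and errors of group means are standard deviations (SD, n = 3). Every fold is relative to the array's own 75th percentile.

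Gene lists, 26 in all with 469 entries of which 438 were tested, were fixed before the data were examined, as were the design, the rule for naming genes and most of the other settings tried. They were antiviral interferon-stimulated genes, interferon-inducible GTPases, MHC class I presentation, MHC class II presentation, interferon receptors and JAK-STAT components, chemokines, inflammatory cytokines and NF-kB targets, TREM and CD300 receptors and adaptors, pattern-recognition receptors and adaptors, cell death and inflammasome genes, immediate-early genes, heat shock and unfolded protein genes, glucocorticoid-responsive genes, sterol synthesis genes, cell cycle genes, the chromosome 16 neighbours of Ifnar2, and 10 lists of cell markers (neutrophil, monocyte, large peritoneal macrophage, B cell, T and NK cell, mast cell, eosinophil, dendritic cell, erythroid, mesothelial and stromal). The TREM and CD300 list was included because members of that receptor family have been linked to this study, so its result is not independent evidence. Ifnar1, Ifngr2 and Il10rb stand both in the JAK-STAT list and among the chromosome 16 neighbours. Lists were tested with fry in limma, whose directional p asks whether the members move on balance in a single direction and whose mixed p asks whether they change in either direction; neither sets a list against other genes. List p values were adjusted over the 26 lists within a comparison. The camera test, with a preset correlation of 0.01 and with an estimated correlation, was run as an alternative. Of the list calls, those that held with an estimated correlation were the antiviral and GTPase lists in wild type, in the comparison of responses and after PBS, the chemokine and inflammatory lists in both genotypes, and the cell death list in wild type and in the comparison of responses.

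The named genes were Ifnar2 and Ifnar1; per comparison of 2 groups, the 8 largest rises and the 8 largest falls among genes that passed the test, had 3 values of a group all above the 3 of the other, and had a symbol that is not a clone or predicted-gene name; the 6 largest positive and the 6 largest negative differences between responses; and up to 4 members per list and comparison with the smallest p. A few genes that this rule takes are not reported here, though counts include them. Where no probe of a gene was well above background on any array of a group, only a bound is given, written as "at least N-fold". The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

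Slides and scans were taken from the file headers. Slide 1 held the 3 wild-type PBS arrays and replicate 1 of wild-type IFN-β, slide 2 held replicates 2 and 3 of wild-type IFN-β and replicate 1 of both knockout groups, and slide 3 held replicates 2 and 3 of both knockout groups; each slide was scanned in its own session. Both knockout groups are balanced over slides, only slide 1 holds both wild-type groups, and no slide holds both PBS groups. Slide was fitted as a fixed and as a random block, and list values were also taken within slides. The groups share replicate numbers in the labels. Deviations from the group means correlated between same-numbered arrays of the Ifnar2-/- groups at r = 0.51, 0.19 and 0.10, each over 0.1, so the numbers were taken to pair those arrays (pair 1 lies on slide 2 and the other pairs on slide 3). The highest correlation with an array of another number was -0.26 for pair 1, 0.22 for pair 2 and 0.12 for pair 3, so that pair 1 alone correlated best with its own number. The wild-type pairs gave r = 0.03, -0.12 and -0.12, and over all 18 same-numbered pairs of groups 5 exceeded 0.1. A fit with the replicate number as a block was run as an alternative, and for Ifnar2-/- it was also run on its 6 arrays alone.

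The other settings tried were normexp background correction (offset 50), quantile normalization, no filter on dim probes, a filter to probes well above background on all 12 arrays, the mean of a gene's probes, every probe on its own, slide as a fixed or random block, the replicate block, only the arrays of the groups compared, array weights, a trend and robust variance, outlier spots kept, an adjusted p under 0.01, at least a 2-fold change, the set tests, and leaving out each array in turn. Settings chosen after seeing the data were no scaling between arrays, leaving out both arrays with a high neutrophil marker signal (wild-type PBS replicate 1 and Ifnar2-/- IFN-β replicate 3), and fits of the 6 Ifnar2-/- arrays with a replicate block or with slide as a fixed block.

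The scripts were tested on simulated data over 18276 genes, with known changes added to 1 comparison at a time. Before these changes each gene had the same mean, taken from the real data, in all groups. The real differences between groups were therefore absent, and correlation between arrays of a slide was not tested. For the wild-type comparison, 14.3% of the genes changed 1.5-fold were called, 52% of those changed 2-fold, 76% of those changed 3-fold and 86% of those changed 4-fold, with 6 unchanged genes among 123 calls. For the Ifnar2-/- comparison the shares were 20.4%, 46%, 76% and 82%, with 7 unchanged genes among 121 calls.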

Results

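Gene expression was measured in peritoneal exudate cells, the leukocytes and shed lining cells washed out of the abdominal cavity, taken from female mice 3 hours after an injection of IFN-β or PBS into that cavity. Wild-type and Ifnar2-/- mice were compared, with 3 arrays from different mice in each of the 4 groups. Ifnar2 and Ifnar1 encode the subunits of the receptor for type I interferons, and the design asks which responses to IFN-β need Ifnar2 and which take place without it. Each array held 43379 spots for 41174 probes. Between 59.4% and 71.6% of the spots were well above background, and 18276 genes were tested. The share was lower on slide 3 (59.4% to 62.5%), which held Ifnar2-/- arrays alone, than on the other slides (65.2% to 71.6%). Arrays of a group correlated at r = 0.987 to 0.991 after PBS and 0.988 to 0.993 after IFN-β in wild type, and at r = 0.986 to 0.991 and 0.974 to 0.986 in Ifnar2-/-. These correlations are across genes, which are not independent replicates. The first principal component held 56.1% of the variance between arrays and the second held 17.2%.

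The targeted gene gave opposite differences on its probes. Probe A_52_P190405 (chromosome 16, 91444402 to 91444461) lay at 4.64 ± 0.23 (log2 units above the array's 75th percentile, SD, n = 3) after PBS in wild type and at 2.79 ± 0.14 in Ifnar2-/-. The difference of -1.85 (SE 0.14) passed limma's test with an adjusted p of 5.47e-05 among all probes. Probe A_51_P338924 (chromosome 16, 91455837 to 91455896) lay at 1.64 ± 0.07 in wild type and at 2.59 ± 0.10 in Ifnar2-/-, a difference of 0.96 (SE 0.18, adjusted p = 0.0149). After IFN-β the first probe gave 4.65 ± 0.14 in wild type and 3.05 ± 0.14 in Ifnar2-/-, and the second gave 1.38 ± 0.36 and 2.91 ± 0.25. Both probes were well above background on all 12 arrays. Where the probes lie relative to the deleted part of Ifnar2 is not given in the sources used here, so a probe outside it would check nothing. With slide as a fixed block the first probe's difference was -1.80 and missed the threshold (adjusted p = 0.077). In a separate setting without that block, the mean of the gene's probes gave -0.45 and also missed it (adjusted p = 0.13). Ifnar1 did not pass the test in any comparison: its log2 difference was 0.20 after PBS (adjusted p = 0.566), -0.18 for IFN-β in wild type (0.459) and 0.28 for IFN-β in Ifnar2-/- (0.434).

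**Figure D1:**
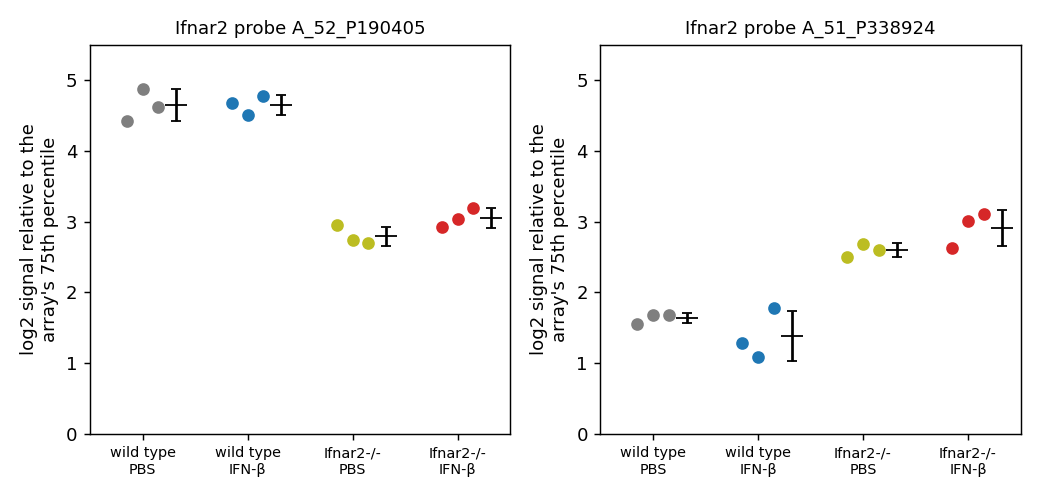
Signal of both Ifnar2 probes on each of the 12 arrays, in log2 units relative to the array's 75th percentile, by group; points are arrays and bars are the group mean with its SD. The left panel's probe has PBS means of 4.64 in wild type and 2.79 in Ifnar2-/-, whereas the right panel's probe has 1.64 and 2.59.

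In wild-type cells IFN-β raised antiviral genes and chemokines by the largest margins. Cxcl10, a chemokine that attracts activated T cells through CXCR3, rose by a log2 fold change of 13.75 (SE 0.50, adjusted p = 2.07e-08), although it was well above background on 1 of 3 PBS arrays. Rsad2, which encodes the antiviral enzyme viperin, rose by 11.71 (SE 0.38, adjusted p = 1.24e-08), and Ccl7, which attracts monocytes, rose by 11.15 (SE 0.62, adjusted p = 4.16e-07). Among falls, Il1r1, the signalling receptor for interleukin 1, was at least 61.4-fold lower after IFN-β (adjusted p = 1.18e-05), and Nr1d1, a repressor in the circadian clock, was lower by a log2 fold change of -3.81 (SE 0.19, adjusted p = 1.87e-07). In all, 7205 genes passed the test, 39.4% of those tested, with 3217 higher and 3988 lower; 1597 rose and 1667 fell at least 2-fold.

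Other leading rises were Ccl12, another monocyte chemokine, which was at least 1406-fold higher (adjusted p = 9.08e-09), and Cxcl11, a further CXCR3 ligand, at least 510-fold higher (adjusted p = 7.67e-08). Ifit3, Ifit1 and Ifit2, which encode antiviral proteins, rose by 10.11, 10.11 and 9.81. Other leading falls were Sox7, a transcription factor, at least 13.6-fold lower, Aph1c, a component of γ-secretase, at least 8.33-fold lower, and Dixdc1 at least 4.92-fold lower. Cables1 and Lama3, a laminin chain, had log2 fold changes of -4.10 (SE 0.35) and -3.77 (SE 0.47). Ifnlr1, a receptor subunit for interferon lambda, was at least 3.18-fold lower (adjusted p = 0.000286), which normexp background correction ended (adjusted p = 0.09). These leading genes, like those of the other comparisons of 2 groups, were chosen among genes whose 3 values in a group all lay above the 3 of the other, so that separation is no further result.

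All 39 antiviral interferon-stimulated genes tested rose in wild type, with a median log2 fold change of 4.96 (fry adjusted p = 2.8e-10), and all 39 also passed when adjusted over the list alone. Examples are Isg15, a ubiquitin-like modifier (8.66), Oasl1 (8.05), Zbp1, a sensor of Z-form nucleic acid (6.09), and Isg20, a ribonuclease (5.54). All 15 interferon-inducible GTPases, proteins that attack vacuoles of pathogens, rose as well, with a median of 4.89 (fry adjusted p = 2.8e-10) and 15 when adjusted over the list alone; Gbp4 gave 6.01, Irgm1 4.89, Irgm2 4.75 and Igtp 4.49. Within slide 1, the only slide with both wild-type groups, the medians were 5.05 for the antiviral list and 5.05 for the GTPases, from 1 IFN-β array and 3 PBS arrays.

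Chemokines rose in wild type: 12 of 19 were higher, 0 were lower and 7 were not called, with a median of 0.99, or 0.54 over probes well above background on all 12 arrays (fry adjusted p = 2.72e-08; 12 adjusted over the list alone). Besides Cxcl10, Cxcl11 and Ccl12, Cxcl9, well above background on 1 of 3 PBS arrays, rose by 8.75. Of 32 inflammatory cytokines and NF-kB targets, 22 were higher and 10 not called, with a median of 1.28 (fry adjusted p = 4.83e-07; 23 higher adjusted over the list alone). They included Acod1, the enzyme that makes itaconate (9.17), the cytokine Il6 (5.51), Il18 (2.80) and the costimulatory receptor Cd40 (2.63). Within slide 1 the medians were 1.10 for chemokines and 1.38 for the inflammatory list.

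Cell death and inflammasome genes rose, with 16 of 22 higher, 1 lower and 5 not called (median 1.12, fry adjusted p = 1.98e-08; 16 higher and 1 lower adjusted over the list alone). Tnfsf10, the death ligand TRAIL, gave 5.91, Mlkl, the executor of necroptosis, 4.49, Casp4 2.59 and Casp8 2.02. MHC class I presentation genes rose, with 14 of 16 higher and 2 not called (median 1.27, fry adjusted p = 8.38e-07; 15 adjusted over the list alone), but the list had an adjusted p = 0.0853 with an estimated correlation. The peptide transporter genes Tap1 and Tap2 gave 3.31 and 2.11, Tapbpl 2.37 and the immunoproteasome subunit Psmb8 2.11; within slide 1 the list's median was 1.39. Pattern-recognition receptors and adaptors rose, with 13 of 22 higher, 2 lower and 7 not called (median 0.92, fry adjusted p = 2.43e-06; 14 and 2 adjusted over the list alone; adjusted p = 0.160 with an estimated correlation). Tlr3, the endosomal sensor of double-stranded RNA, gave 5.07, the DNA sensor Cgas 2.90, the adaptor Myd88 2.48 and Nod1 2.44.

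Interferon receptors and JAK-STAT components went both ways, with 9 of 23 higher, 6 lower and 8 not called (10 and 7 adjusted over the list alone). Their median was 0.05, and -0.12 under quantile normalization or -0.11 with no scaling (fry adjusted p = 0.000701, upward; adjusted p = 0.688 with an estimated correlation). Both of those scalings ended the list's call (0.96 and 0.45). Socs1, a feedback inhibitor of the pathway, gave 5.40, Irf1 2.69, Jak2 1.32 and Ifngr1 -1.14. Heat shock and unfolded protein genes rose, with 10 of 13 higher, 1 lower and 2 not called (10 and 1 adjusted over the list alone), a median of 0.53, or 0.29 under quantile normalization, and fry adjusted p = 0.00311 (adjusted p = 0.660 with an estimated correlation). With slide as a fixed block that call was lost (0.072). Hspa1a gave 4.07, Hspa5 1.14, Hsp90aa1 0.96 and Xbp1 0.76.

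The TREM and CD300 receptors and adaptors, myeloid receptors of which some activate and some inhibit, had 2 of 11 higher, 4 lower and 5 not called, the same when adjusted over the list alone. Their median was -0.24, or -0.41 with no scaling and -0.01 with slide as a fixed block. The call (fry adjusted p = 0.0331) held in 18 of 26 other settings and not with that block. This list was chosen because of this study and is not independent evidence. Treml1 gave -2.93, Cd300a -0.82, Cd300ld -0.82 and Cd300lf 2.03. Chromosome 16 neighbours of Ifnar2 fell on balance, with 2 of 15 higher, 4 lower and 9 not called, the same adjusted over the list alone, and a median of -0.18, or -0.35 with no scaling and -0.10 with slide as a fixed block (fry adjusted p = 0.0135; adjusted p = 0.733 with an estimated correlation). Dnajc28 gave -2.59, Il10rb -0.93, Itsn1 -0.87 and Mrps6 0.62, while the mean of all probes of Itsn1 gave 0.64.

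Several functional lists had members that passed in wild type while the list did not, though MHC class II genes passed as a list in 5 of 26 other settings, sterol synthesis genes in 4 and immediate-early genes in 3. MHC class II presentation had 3 of 11 lower (3 adjusted over the list alone; median -0.35, fry adjusted p = 0.0728), with H2-DMb2 at -1.01, H2-Ob at -0.77 (-0.31 with normexp, adjusted p = 0.255) and H2-DMb1 at -0.61. Sterol synthesis genes had 2 of 18 higher and 7 lower, the same adjusted over the list alone (median -0.35, fry adjusted p = 0.0674). Dhcr7 gave -1.33 and Lss -0.75. Immediate-early genes had 5 of 19 higher and 1 lower, the same adjusted over the list alone (median 0.31, and -0.05 under quantile normalization; fry adjusted p = 0.116). Atf3 gave 3.00, Jun 1.97, Zfp36 1.44 and Dusp1 -1.93. Glucocorticoid-responsive genes had 3 of 10 higher and 5 lower (4 and 5 adjusted over the list alone; median -0.86, fry adjusted p = 0.431), with Ddit4 at -2.12, Tsc22d3 at -1.89, Sgk1 at 1.34 and Mt1 at 1.91, or 0.09 as the mean of its probes (adjusted p = 0.881). Of 24 cell cycle genes, the replication helicase subunits Mcm6 (1.44) and Mcm2 (0.76) were higher, also adjusted over the list alone; the list's median was -0.05 with a mean of 0.05 (fry adjusted p = 0.681).

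Among cell markers, monocyte markers rose in wild type: 5 of 9 were higher and 4 not called (5 adjusted over the list alone), with a median of 1.32 (fry adjusted p = 2.43e-06; adjusted p = 0.0582 with an estimated correlation). Chil3 gave 3.46, Ms4a6c 3.14, Ly6c1 1.46 and Plac8 1.32. B cell markers fell, with 6 of 16 lower (7 adjusted over the list alone, median -0.56, fry adjusted p = 0.0482, or 0.257 with slide as a fixed block). Among them were Fcer2a (-2.45), Ebf1 (-2.21) and Cr2 (-2.09). Mast cell markers had 1 of 14 higher and 3 lower, the same adjusted over the list alone. Their median was -0.28, or -0.48 under quantile normalization (fry adjusted p = 0.0292, downward, or 0.278 with slide as a fixed block). Mrgprb2 gave -1.35, Kit -1.11 and Tph1 1.86. Mesothelial and stromal markers fell, with 4 of 11 lower, also 4 adjusted over the list alone. Their median was -0.24, or -0.10 with normexp (fry adjusted p = 0.0473), and -0.54 with slide as a fixed block (0.141). Krt8 gave -1.15 and Krt19 -1.05. Wt1, well above background on 1 of 3 IFN-β arrays, gave -1.09, or -0.07 with normexp (adjusted p = 0.647). Of 26 other settings, the call held in 11 for B cell, 12 for mesothelial and 18 for mast cell markers. By camera none of these lists passed, with a preset correlation (adjusted p = 0.0545 for B cell, 0.229 for the others) or an estimated one (0.733).

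The remaining marker lists did not pass in wild type as analysed, though of 26 other settings the dendritic cell list passed in 9 (lowest fry adjusted p = 0.00122), the T and NK cell list in 2 and the large peritoneal macrophage list in 1. Dendritic cell markers had 1 of 10 higher and 4 lower, the same adjusted over the list alone (median -0.13, or -0.05 with Siglech at its bound; fry adjusted p = 0.0503). Clec9a gave 1.54, Ccr7 -2.06 and Flt3 -1.29. T and NK cell markers had 3 of 21 higher and 8 lower (4 and 8 adjusted over the list alone; median -0.28, fry adjusted p = 0.202), with the activating receptor Klrk1 at 2.72, Thy1 at -2.09 and Cd3g at -1.45. Large peritoneal macrophage markers had 3 of 18 higher and 4 lower, the same adjusted over the list alone (median -0.10, fry adjusted p = 0.431), with Naip1 at -2.29, Rarb at -1.63, Gata6, the factor that specifies these cells, at -1.18, and Selp at 1.06. Neutrophil markers had 2 of 19 higher and 1 lower (1 and 0 adjusted over the list alone), with a median of 0.21, or -0.32 with normexp (fry adjusted p = 0.681). Over 26 other settings that median ran from -0.51 to 1.00. Fpr2 gave 1.69. Neither the 6 eosinophil markers (median 0.22, fry adjusted p = 0.852) nor the 5 erythroid markers (median 1.97, fry adjusted p = 0.611) had a member that passed, over all genes or over the list alone.

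Scaling set part of the direction in wild type. The median log2 fold change of all genes was -0.04 as analysed, -0.13 under quantile normalization and -0.21 with no scaling; 44.6% of the genes that passed were higher as analysed, 36.6% under quantile normalization and 30.6% with no scaling. With slide as a fixed block 4427 genes passed, 4267 of them among the 7205. Over the 7205 genes the fold change with that block had a median of 1.02 times that without it and the same sign in each, while its SE had a median of 1.46 times. Of 105 named genes 90 kept their call; H2-DMb1, H2-Ob, Cd300a, Cd300ld, Hspa5, Hsp90aa1, Sgk1, Lss, Mcm2, Mrps6, Cd177, Csf3r, Kit, Tph1 and Mcpt4 did not. Quantile normalization also ended the call of Hsp90aa1 (0.56, adjusted p = 0.0684) and gave 0.63 for Selp, 0.49 for Xbp1 and -0.99 for H2-DMb1, and no scaling ended the calls of Mcm2 and Mrps6. With normexp Clec9a gave 0.48, Klrk1 1.36, Flt3 -0.40, Dnajc28 -1.57 and Cxcl9 5.77, and as the mean of a gene's probes Nr1d1 gave -1.51, Lama3 -2.06, Ebf1 -1.26 and Ly6c1 2.79.

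In Ifnar2-/- cells inflammatory genes and chemokines were higher after the IFN-β injection than after PBS, while antiviral genes as a list did not pass the test. No group received the preparation without active interferon, so IFN-β and another constituent of the injection cannot be told apart here. Acod1 rose by a log2 fold change of 6.18 (SE 0.55, adjusted p = 0.000727), Il6 by 3.47 (SE 0.28, adjusted p = 0.000468), and Cxcl1 and Cxcl2, ligands of the neutrophil receptor CXCR2, by 2.82 and 2.74 (SE 0.23, adjusted p = 0.000468 for each). Cxcl10, well above background on 1 of 3 PBS arrays, rose by 3.50 (SE 0.50, adjusted p = 0.0132), or 1.15 with normexp. Inflammatory cytokines and NF-kB targets had 18 of 32 higher, 0 lower and 14 not called, with a median of 1.33 (fry adjusted p = 1.22e-05), and 23 higher adjusted over the list alone. Chemokines had 10 of 19 higher, 0 lower and 9 not called, with a median of 1.98 (fry adjusted p = 1.82e-05), and 14 higher adjusted over the list alone. The chemokine median was 0.87 with normexp and 1.32 without Ifnar2-/- IFN-β replicate 3, the array of highest neutrophil marker signal. Neutrophil markers also had a median of 1.98, which did not pass by fry (adjusted p = 0.104). The neutrophil list passed by camera with the preset correlation (adjusted p = 3.70e-06). With genes not well above background at their bound the inflammatory and chemokine medians were 1.08 and 1.80. In all, 207 genes passed, 1.13% of those tested, with 169 higher and 38 lower; 113 rose and 20 fell at least 2-fold.

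The leading rises in Ifnar2-/- also included Cxcl3, another CXCR2 ligand, at least 15.1-fold higher (adjusted p = 0.0205), and Flrt3 at least 12.1-fold higher (adjusted p = 0.000468). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was at least 10.2-fold higher (adjusted p = 0.026), and Slc7a11, the cystine and glutamate exchanger, at least 9.92-fold higher (adjusted p = 0.0488). Ccl7 rose by 4.39 (SE 0.62) and the secreted protein gene Prok2 by 4.28 (SE 0.65), and Dcstamp, which acts in fusion of macrophages and osteoclasts, was at least 5.54-fold higher. Among falls, Klf15 gave -2.22 (SE 0.38), Arl11 -1.60, the muscle ubiquitin ligase gene Fbxo32 -1.47 (SE 0.18), Pik3ip1, an inhibitor of PI3K, -1.41, and Mgst2 -1.23. Prickle2 gave -2.59 (SE 0.39) and was well above background on 1 of 3 IFN-β arrays. Fabp5, a fatty acid binding protein gene, was at least 1.9-fold lower (adjusted p = 0.0133), and Thsd1, well above background on 2 of 3 PBS arrays, at least 1.5-fold lower (adjusted p = 0.0133).

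The inflammatory list kept its call in all 28 other settings run in Ifnar2-/- and the chemokine list in 27, while the number of genes called varied widely. It was 13 when the 6 Ifnar2-/- arrays were fitted alone, 0 in those arrays with the replicate number as a block (2800 at an unadjusted p under 0.05), 2 in them with slide as a block, and 32 to 293 when an array was left out. In the block fit of the 6 arrays none of the 33 named genes that had passed kept its call, with Acod1 at an adjusted p of 0.052; the inflammatory list did (median 1.33, fry adjusted p = 0.0292) and the chemokine list did not (median 1.98, 0.0953). Among named genes the call held in 7 of 28 other settings for Mgst2 and for Cmpk2, 9 of 28 for Itgax and 9 of 27 for Slc7a11. For Cxcl3 and for Ptgs2 it held in 17 of 27. Normexp ended the calls of Slc7a11 (adjusted p = 0.128), Dcstamp (0.0831) and Thsd1 (0.131), and with it Klf15 gave -1.35, Prickle2 -1.05 and Cmpk2 -0.72. Single arrays that moved the count by more than 1.5 times were PBS replicates 2 (32 genes without it), 1 (59) and 3 (79) of Ifnar2-/-, and wild-type IFN-β replicate 1 (122) and wild-type PBS replicates 1 and 2 (131 each), which enter through the shared spread. Within slides the inflammatory median was 1.33 on slide 2 (1 array per group) and 1.31 on slide 3 (2 per group), and the chemokine median was 1.14 and 2.31.

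Antiviral interferon-stimulated genes in Ifnar2-/- had 1 of 39 higher, 1 lower and 37 not called, the same adjusted over the list alone. Their median was -0.11, or -0.04 with genes at their bound and 0.01 with no scaling (fry adjusted p = 0.805), although the mixed test for change in either direction gave 0.00155. Oasl1, well above background on 1 of 3 PBS arrays, rose by 1.79 (adjusted p = 0.00221), or 0.39 with normexp (adjusted p = 0.134), and Cmpk2, a mitochondrial nucleotide kinase gene, was lower at -1.20 (adjusted p = 0.0458). None of the 15 interferon-inducible GTPases passed by limma (median 0.06, fry adjusted p = 0.798), nor did 16 MHC class I genes (-0.02, or 0.10 with no scaling, adjusted p = 0.798) or 11 MHC class II genes (-0.19, adjusted p = 0.693), over all genes or over the list alone. JAK-STAT components had 0 of 23 called, but 4 higher and 1 lower adjusted over the list alone (median 0.16, fry adjusted p = 0.0814, and 0.0196 in the 1 of 28 other settings where the list passed). Socs3 stood at 1.15 (adjusted p = 0.0501).

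**Figure D2:**
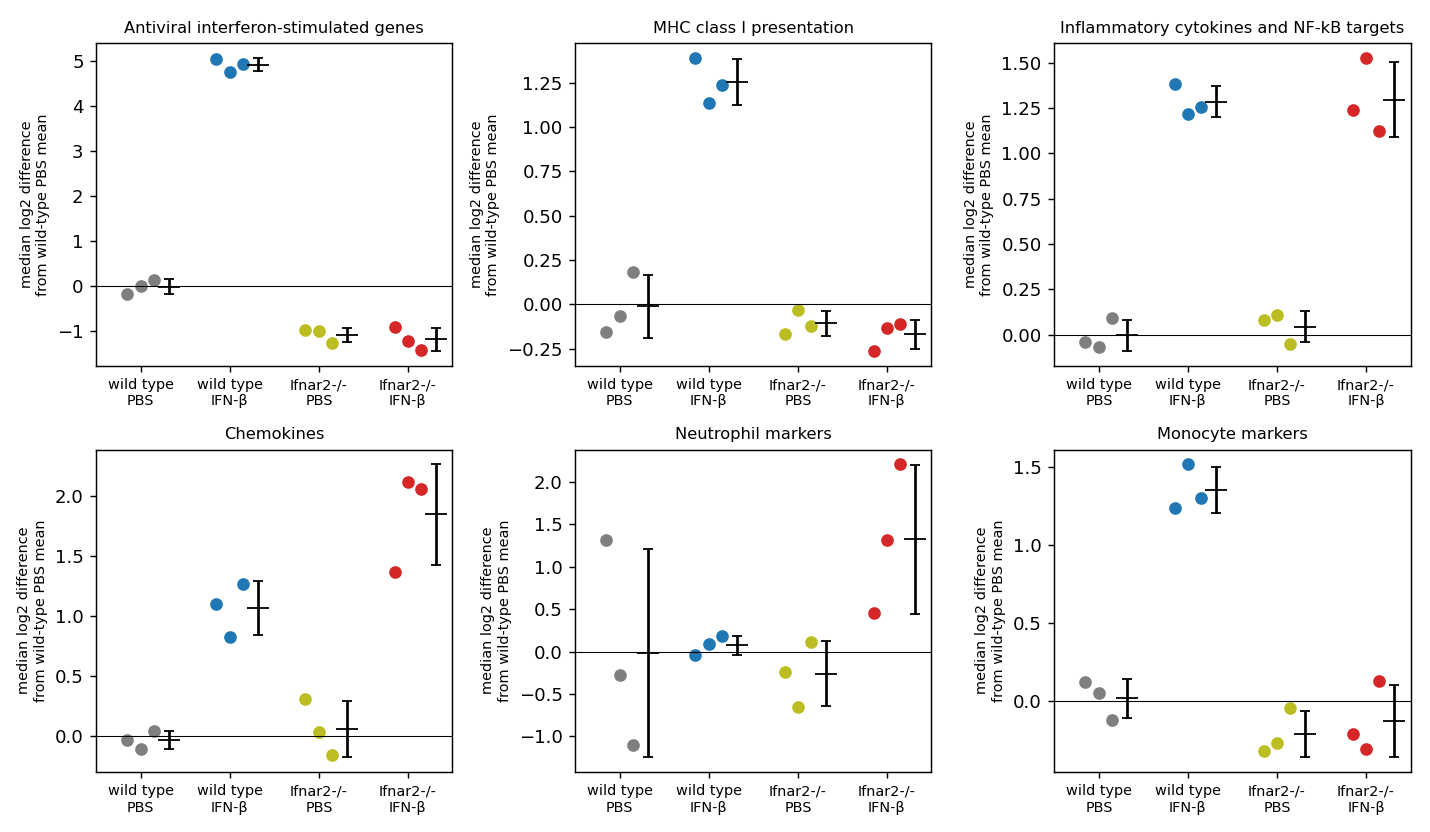
Median over the members of 6 gene lists on each array, as the log2 difference from the mean of the wild-type PBS arrays; points are the 12 arrays and bars the group mean with its SD. The antiviral list and the monocyte markers stand apart in wild type after IFN-β (median log2 fold changes 4.96 and 1.32), and the inflammatory list is higher after IFN-β in both genotypes (1.28 and 1.33).

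Other functional lists in Ifnar2-/- did not pass as analysed, though single members did, and of 28 other settings the immediate-early and heat shock lists passed in 2 each and the TREM and CD300 list in 1. Pattern-recognition genes had 3 of 22 higher (5 higher and 2 lower adjusted over the list alone; median -0.04, or 0.07 with no scaling, mean 0.20, fry adjusted p = 0.180): Myd88 rose by 0.75, Tlr2 by 1.39 and the lipopolysaccharide co-receptor Cd14 by 1.88. The TREM and CD300 list had 1 of 11 higher (3 adjusted over the list alone), with a median of -0.14 and a mean of 0.65 (fry adjusted p = 0.0814; 0.029 in the 6 arrays with the replicate block). Treml4 rose by 2.30 (SE 0.26, adjusted p = 0.00288) and Trem1, an amplifier of inflammatory signals, stood at 3.43 (SE 0.76, adjusted p = 0.0637). Cell death genes had 1 of 22 higher, Casp4 at 0.78 (1 higher and 1 lower adjusted over the list alone; median 0.08, fry adjusted p = 0.126). Immediate-early genes had 1 of 19 higher, Nr4a1 at 2.23 (5 adjusted over the list alone; median 0.48, fry adjusted p = 0.0814, and 0.029 with the replicate block). Heat shock genes had 1 of 13 higher, Hspa1a at 1.65 (5 adjusted over the list alone; median 0.33, 0.0776, and 0.011 with the replicate block). Glucocorticoid-responsive genes had 1 of 10 higher, the metallothionein Mt2 at 3.14 (3 higher and 1 lower adjusted over the list alone; median -0.48, mean 0.32, 0.981). No member passed over all genes among sterol synthesis genes (median 0.17, fry adjusted p = 0.693; 2 higher and 1 lower adjusted over the list alone), cell cycle genes (0.13, adjusted p = 0.798) and chromosome 16 neighbours (0.19, adjusted p = 0.155), the last pair of lists having 0 adjusted over the list alone too.

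Neutrophil markers had a median of 1.98 in Ifnar2-/-, but the arrays spread widely and 0 of 19 passed, also adjusted over the list alone (fry adjusted p = 0.104). Ngp stood at 3.67 (SE 1.10, adjusted p = 0.133) and Lcn2 at 2.19 (SE 0.67, adjusted p = 0.139). The median was 0.80 on slide 2 and 2.90 on slide 3, where 18 of 19 members were higher. With both arrays of high neutrophil marker signal left out (wild-type PBS replicate 1 and Ifnar2-/- IFN-β replicate 3) 125 genes passed, 97 of them among the 207. The chemokine median was then 1.32 (fry adjusted p = 0.000283) and the inflammatory median 1.36 (0.000265). Of 10 dendritic cell markers the integrin gene Itgax rose by 1.46 (adjusted p = 0.0412; 2 adjusted over the list alone; list median 0.02, or -0.01 with normexp, fry adjusted p = 0.209). Mesothelial and stromal markers had 0 of 11 called and 3 lower adjusted over the list alone (median -0.60, fry adjusted p = 0.0653), and the list passed in 4 of 28 other settings (lowest 0.024). Large peritoneal macrophage markers had 0 of 18 called and 1 higher adjusted over the list alone (-0.17, adjusted p = 0.693). No marker passed, over all genes or over the list alone, among monocyte (0.02, or -0.01 with normexp, adjusted p = 0.798), B cell (-0.18, adjusted p = 0.726), T and NK cell (-0.18, adjusted p = 0.730), mast cell (-0.12, adjusted p = 0.613), eosinophil (0.39, adjusted p = 0.721) and erythroid (0.94, adjusted p = 0.798) lists. Of all genes that passed in Ifnar2-/-, 81.6% were higher as analysed, 66.8% with normexp.

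The difference between the responses, tested as an interaction, was largest for the antiviral genes that rose in wild type. Rsad2 had a difference (Ifnar2-/- response minus wild-type response) of -11.34 (SE 0.54, adjusted p = 5.31e-07), Ifit3 of -11.22 (SE 0.71), Ifit2 of -10.48 (SE 0.58), Ifit1 of -10.46 (SE 0.52) and Cxcl10 of -10.25 (SE 0.70). Each of the 39 antiviral genes had a smaller response in Ifnar2-/- (median difference -5.08, fry adjusted p = 4.2e-09; 39 adjusted over the list alone), and so had each of the 15 GTPases (median -4.77, fry adjusted p = 4.2e-09; 15 adjusted over the list alone). Isg15 gave -8.34, Cmpk2 -9.83, Gbp4 -6.23 and Irgm1 -4.77. In all, 3247 genes passed (17.8%), with 1586 positive and 1661 negative differences, and 3101 of these had also passed in wild type.

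Largest in the other direction was Il1r1 with a difference of 5.74 (SE 0.92, adjusted p = 0.00174). It was followed by Cxcl3 at 5.60 (SE 1.28, adjusted p = 0.0126), Ngp, a neutrophil granule protein gene, at 5.10 (SE 1.56, adjusted p = 0.0465), Sox7 at 4.49, Ifnlr1 at 4.25 and the gap junction gene Gja1 at 4.12. All of these except Ngp rest partly on groups in which the gene was not well above background, as do Cxcl11 (-10.71), Ifit1, Ccl12 and Siglech, so their sizes are fitted values and not bounds. Slide as a fixed block ended the calls of Cxcl3 (adjusted p = 0.078), Ngp (0.13) and Gja1 (0.071), and Ngp passed in 9 of 24 other settings, with values from 1.75 to 6.10. Normexp ended the calls of Sox7 (0.67, adjusted p = 0.306), Ifnlr1 (0.69, adjusted p = 0.156) and Gja1 (1.28, adjusted p = 0.0631) and gave 2.46 for Il1r1 and 2.38 for Cxcl3.

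Inflammatory genes did not pass the directional test of the difference as a list: 3 of 32 had a larger and 7 a smaller response in Ifnar2-/-, with 22 not called (3 and 8 adjusted over the list alone). Their median difference was -0.20, or 0.05 under quantile normalization and 0.08 with no scaling (fry adjusted p = 0.0565), while the mixed test gave 3.88e-12. The list passed in 4 of 25 other settings: probes above background on all 12 arrays (0.041), slide as a fixed block (0.048), array weights (0.018), and without Ifnar2-/- IFN-β replicate 2 (0.0072). Il18 (-3.01), Cd40 (-2.45) and Il6 (-2.04, SE 0.39, adjusted p = 0.00473) had smaller responses in Ifnar2-/-, and Irak3, a brake on Toll-like receptor signalling, a larger one (1.17). Chemokines had smaller responses on balance, with 3 of 19 positive, 8 negative and 8 not called (4 and 9 adjusted over the list alone; median -0.68, or -0.43 under quantile normalization and -0.40 with no scaling; fry adjusted p = 2.06e-05; adjusted p = 0.192 with an estimated correlation). Cxcl9 gave -6.77, and the fitted value of Ccl12 was -8.67. That call was lost when probes had to be well above background on all 12 arrays (median -0.11, 0.0894).

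Cell death genes had smaller responses in Ifnar2-/-, with 12 of 22 negative (1 positive and 13 negative adjusted over the list alone; median -0.88, fry adjusted p = 8.36e-07), among them Tnfsf10 (-6.95) and Mlkl (-4.39). MHC class I genes did so too, with 11 of 16 negative (13 adjusted over the list alone; median -1.43, fry adjusted p = 1.57e-05; adjusted p = 0.0706 with an estimated correlation), such as Tap1 at -3.47 and Psmb8 at -2.09. Pattern-recognition genes had 1 of 22 positive and 10 negative, the same adjusted over the list alone (median -0.23, or 0.05 with no scaling and -0.47 without both arrays of high neutrophil signal; fry adjusted p = 0.000219; adjusted p = 0.265 with an estimated correlation), with Tlr3 at -5.32, Cgas at -2.51 and Nod1 at -2.48. Monocyte markers had 3 of 9 negative (4 adjusted over the list alone; median -1.37, or -0.79 without wild-type PBS replicate 3; fry adjusted p = 9.57e-05; adjusted p = 0.0706 with an estimated correlation), with Ms4a6c at -2.89. JAK-STAT components had 3 of 23 positive and 6 negative (5 and 8 adjusted over the list alone), a median of 0.10 and a mean of -0.14 (fry adjusted p = 0.114, passing in 4 of 25 other settings, lowest 0.00417). Socs1 gave -4.27, Irf1 -2.42 and Jak2 -1.35.

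Positive differences on balance were found for the TREM and CD300 list, with 3 of 11 positive and 8 not called, also 3 adjusted over the list alone (median 0.86, or 0.55 with array weights and 0.54 without Ifnar2-/- IFN-β replicate 3; fry adjusted p = 0.00779; adjusted p = 0.390 with an estimated correlation). Treml4 gave 2.54 (SE 0.36, adjusted p = 0.000821), Treml1 2.37 and Cd300a 1.21. Slide as a fixed block ended this call (0.058), and so did leaving out both arrays of high neutrophil signal (median 0.53, 0.11). Chromosome 16 neighbours had 5 of 15 positive (6 adjusted over the list alone; median 0.46, fry adjusted p = 0.0103, but 0.24 with normexp, 0.09 with array weights, 0.03 with slide as a fixed block and 0.74 with no scaling; adjusted p = 0.481 with an estimated correlation). Among them were Dnajc28 (1.86, or 0.91 with normexp, adjusted p = 0.0548), Itsn1 (1.06, or -0.48 as the mean of its probes) and Rcan1 (1.05). Dendritic cell markers had 3 of 10 positive and 1 negative, the same adjusted over the list alone (median 0.47, or 0.75 with no scaling; fry adjusted p = 0.0268; adjusted p = 0.588 with an estimated correlation), with Ccr7 at 2.05, Clec9a at -0.88 and a fitted 2.58 for Siglech, or 0.23 with normexp (adjusted p = 0.453). That call held in 14 of 25 other settings, and normexp (median 0.17, 0.14), slide as a fixed block and the replicate block (0.07) were among those that ended it.

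The other lists did not pass the directional test of the difference as analysed, though of 25 other settings sterol synthesis genes passed in 3 (lowest fry adjusted p = 0.0321) and T and NK cell markers in 1 (0.041). Members that passed were Nr4a1 (1.78), Fos (1.26), Atf3 (-1.77) and Zfp36 (-0.96) among 5 of 19 immediate-early genes (5 adjusted over the list alone; median 0.17, fry adjusted p = 0.751). Hspa1a (-2.43) and Herpud1 (1.03) passed among 13 heat shock genes (median -0.22, or 0.04 under quantile normalization, adjusted p = 0.478), and Sgk1 (-1.62) among 10 glucocorticoid-responsive genes (0.72, adjusted p = 0.705). Mvd (1.17) was among 2 of 18 sterol synthesis genes that passed (1 adjusted over the list alone; 0.51, adjusted p = 0.097). Mcm6 (-1.56) passed among 24 cell cycle genes (0.20, with the test directed downward, adjusted p = 0.945). Large peritoneal macrophage markers had 3 of 18 positive and 1 negative (3 and 2 adjusted over the list alone; median -0.14, or 0.14 with no scaling, adjusted p = 0.945), with Naip1 at 2.06 and Gata6 at 1.41. B cell markers had 3 of 16 positive (4 adjusted over the list alone; 0.41, adjusted p = 0.343) with Fcer2a at 2.26. T and NK cell markers had 4 of 21 positive and 1 negative, the same adjusted over the list alone (0.11, adjusted p = 0.719), with Thy1 at 1.78 and Klrk1 at -2.33. Mrgprb2 (0.97) passed among 14 mast cell markers (0 adjusted over the list alone, median 0.21, adjusted p = 0.420). Ngp passed among 19 neutrophil markers (0 adjusted over the list alone, median 1.70, adjusted p = 0.343). The neutrophil median ran from 0.43 to 2.39 over 25 other settings. Over all genes and over the list alone none passed among MHC class II genes (0.24, adjusted p = 0.531), eosinophil (-0.12, or 0.16 with no scaling, adjusted p = 0.882), erythroid (-0.99, adjusted p = 0.945) and mesothelial markers (0.13, or -0.09 with normexp, adjusted p = 0.945).

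Of the 169 genes higher in Ifnar2-/- after IFN-β, 116 were also higher in wild type (68.6%), where independent lists would share 29.7 (Fisher's exact test, p = 8.48e-49). Of the 38 lower genes, 27 were also lower in wild type (71.1%), where 8.29 would be shared by chance (Fisher's exact test, p = 1.20e-10). The comparisons share no arrays, but both use the same spread per gene from the single fit of all arrays. Fisher's test also treats genes as independent, and genes that change together are not. Its p values therefore do not measure agreement between replicates. Among the 116 shared rises, the rise was larger in wild type for 35 and larger in Ifnar2-/- for 5 by the interaction test, and 76 did not pass it. Across genes the log2 fold changes of both genotypes correlated with r = 0.33 and Spearman's rho = 0.38. A further 55 genes passed in Ifnar2-/- and not in wild type, and the interaction passed for 28 of them.

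**Figure D3:**
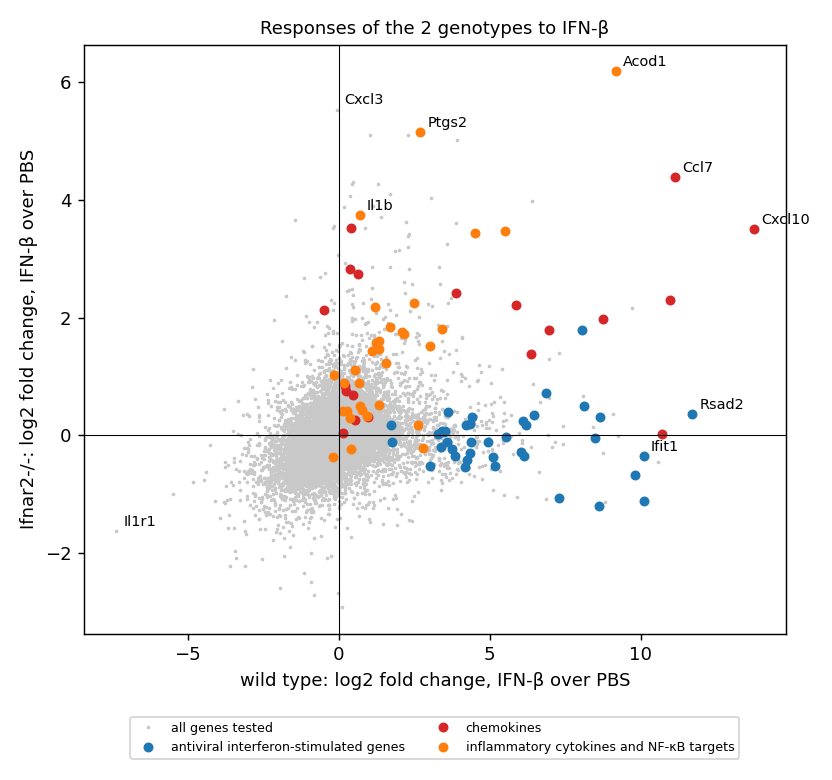
Log2 fold change after IFN-β in wild type (x axis) and in Ifnar2-/- (y axis) for each gene tested, with 3 gene lists coloured; lines mark a change of 0, and fitted values are drawn for genes not well above background. Antiviral genes lie far to the right near 0 on the y axis (medians 4.96 and -0.11), whereas inflammatory genes have medians of 1.28 and 1.33.

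Scaling moved the balance of the interaction. The median difference of all genes was 0.03 as analysed, 0.11 under quantile normalization and 0.31 with no scaling, and the share of positive differences among genes that passed was 48.8%, 56.1% and 71.2%. That share fell to 42.2% with normexp background correction and to 40.4% with slide as a fixed block. With slide as a fixed block 1921 genes passed, 1826 of them among the 3247. Over the 3247 genes the difference with that block had a median of 1.01 times that without it and the same sign in each, while its SE had a median of 1.27 times. Of 78 named genes 51 kept their call. Besides Cxcl3, Ngp and Gja1, those that did not were Irak3, Cd300a, Treml1, Zfp36, Nr4a1, Atf3, Fos, Herpud1, Sgk1, Mvd, Mcm6, Rcan1, Il10rb, Plac8, Gata6, Selp, Rarb, Ebf1, Fcer2a, Cr2, Cd3g, Lat, Mrgprb2 and Clec9a. Several of these also lost their call elsewhere, holding it in 10 of 25 other settings for Zfp36, 11 for Atf3, 13 for Fos and for Mvd, 14 for Rarb, 9 for Cr2 and, of 24, in 10 for Clec9a. Gata6 gave 0.86 as the mean of its probes, Klrk1 -1.31 with normexp, and Zfp36 -0.64 under quantile normalization (adjusted p = 0.111).

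After PBS, Ifnar2-/- cells had lower levels of interferon-stimulated genes than wild-type cells as analysed, but no slide held both groups. With slide as a fixed block the antiviral and GTPase lists both lost their calls. Antiviral genes were lower, with 22 of 39 lower, 0 higher and 17 not called (32 lower adjusted over the list alone), and a median of -1.07, or -0.99 with genes at their bound and -0.56 over probes well above background on all 12 arrays (fry adjusted p = 3.02e-05). Rtp4 gave -6.02 (SE 0.20, adjusted p = 2.01e-07), Oasl1, well above background on 1 of 3 Ifnar2-/- arrays, -4.81, Oas2 -3.62 and Ifi27l2a -3.32. Interferon-inducible GTPases were lower, with 8 of 15 lower and 7 not called (11 adjusted over the list alone; median -0.65, fry adjusted p = 0.000188), such as Gbp2 (-1.14) and Irgm2 (-1.04). In all, 892 genes passed (4.88%), with 520 higher and 372 lower in Ifnar2-/-; 325 and 253 of them differed at least 2-fold.

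The macrophage scavenger receptor gene Marco was higher in Ifnar2-/- by 5.33 (SE 0.32, adjusted p = 1.24e-05), as were Lyve1, a hyaluronan receptor (4.73, SE 0.76), Fgd5 (4.54), Cbr2 (4.14, SE 0.43) and arginase 1, Arg1 (3.99, SE 0.29). Prtg (6.50, SE 0.38) was well above background on 1 of 3 wild-type arrays, and Pianp was at least 12.8-fold higher. H2-Ea, the alpha chain of the MHC class II molecule E, was at least 284-fold lower (adjusted p = 3.24e-07), and Retn, which encodes resistin, at least 25.5-fold lower. Atp6v0e2 gave -6.40 (SE 0.21) and the lectin gene Clec4g -5.61; Ccm2l (-7.04), the lectin gene Cd209a (-6.17) and Ifi44 (-5.52) were each well above background on 1 of 3 Ifnar2-/- arrays. With normexp Prtg gave 3.60, Fgd5 2.91, Ccm2l -4.01, Cd209a -3.55, Ifi44 -2.44 and Oasl1 -2.34, and Clec4g gave -3.07 as the mean of its probes.

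No slide held both PBS groups, and with slide as a fixed block 31 genes passed, 27 of them among the 892. Over the 892 genes the difference with that block had a median of 0.942 times the difference without it (quartiles 0.757 and 1.10) and the same sign in 891, while its SE had a median of 1.98 times the SE without it. Of 51 named genes that had passed, Prtg, Marco, H2-Ea, Ccm2l, Atp6v0e2, Rtp4, Oasl1 and Oas2 then kept their calls and the others did not, while the antiviral median was -0.91 (fry adjusted p = 0.0638) and the GTPase median -0.70 (0.079). Leaving out wild-type PBS replicate 1 or 3 gave 437 or 584 genes, and leaving out Ifnar2-/- PBS replicate 2 or 3 gave 467 or 478.

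Mast cell markers were higher in Ifnar2-/- after PBS, with 3 of 14 higher and 11 not called (12 adjusted over the list alone; median 0.65, fry adjusted p = 0.00146; adjusted p = 0.133 with an estimated correlation). The IgE receptor gene Fcer1a gave 1.48, Hs3st1 1.14 and Kit 0.87. Slide as a fixed block ended this call (median 0.78, 0.078). The remaining lists did not pass as analysed, though JAK-STAT components did so in 2 of 26 other settings (lowest 0.0302). Members that did were Tap2 (1.69) of 16 MHC class I genes (list median -0.14, fry adjusted p = 0.860) and H2-Ob (3.31) of 11 MHC class II genes (0.02, or -0.07 under quantile normalization, adjusted p = 0.456). Irf8 (0.71) and Stat4 (0.86) passed with Ifnar2 and Il10rb (-0.69) of 23 JAK-STAT components (-0.13, adjusted p = 0.281). Ccl12, at least 2.04-fold higher, passed of 19 chemokines (0.25, or 0 with genes at their bound, adjusted p = 0.739). Il1a (3.39, well above background on 2 of 3 wild-type arrays), Cd40 (0.79) and Csf2, which was not well above background in Ifnar2-/-, passed of 32 inflammatory genes (0.04, or -0.01 with normexp, adjusted p = 0.484), and Tlr6 (-0.53) of 22 pattern-recognition genes (0.13, adjusted p = 0.340). Egr1 (1.21) passed of 19 immediate-early genes (-0.01, or 0.09 with no scaling, adjusted p = 0.860). The scavenger receptor Cd163 (2.20) did so of 10 glucocorticoid-responsive genes (0.48, adjusted p = 0.340), and Runx1 (1.65) with Il10rb of 15 chromosome 16 neighbours (0.08, adjusted p = 0.302). In each of these lists the same number passed adjusted over the list alone. Normexp ended the calls of Ccl12 (adjusted p = 0.511) and Csf2 (0.268), and those of Kit and Hs3st1 held in 14 of 26 other settings each. With normexp Il1a gave 1.22 and Hs3st1 0.65, and Il10rb gave -0.28 as the mean of its probes (adjusted p = 0.384).

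Among markers after PBS, Padi4 (0.65), Mmp8 (-3.05) and Csf3r (-0.60) passed of 19 neutrophil markers (2 higher and 2 lower adjusted over the list alone). The neutrophil median was -0.31 (fry adjusted p = 0.835), and it ran from -1.41 to 0.58 over 26 other settings. F13a1 (1.83) passed of 9 monocyte markers (1 and 1 adjusted over the list alone; -0.07, or 0.03 with no scaling, adjusted p = 0.759). Naip1 (1.27), Vsig4 (1.14) and Thbs1 (-3.47) passed of 18 large peritoneal macrophage markers (2 and 2 adjusted over the list alone; -0.10, with the test directed upward, adjusted p = 0.860). Clec9a (1.24), Siglech (1.18) and Cd209a passed of 10 dendritic cell markers (3 higher and 2 lower adjusted over the list alone; median 0.30, mean -0.27, adjusted p = 0.519). Txk (0.91) passed of 21 T and NK cell markers (1 adjusted over the list alone; 0.43, adjusted p = 0.340) and Siglecf (-1.87) of 6 eosinophil markers (1 adjusted over the list alone; -0.42, adjusted p = 0.378). No member passed, over all genes or over the list alone, of the TREM and CD300 list (0.01, or -0.01 with normexp, adjusted p = 0.860), cell death genes (0.05, adjusted p = 0.302), and heat shock genes (-0.09, or 0.01 with no scaling, adjusted p = 0.759). The same held for sterol synthesis genes (-0.20, adjusted p = 0.378), cell cycle genes (-0.72, adjusted p = 0.375), and B cell (-0.16, adjusted p = 0.759), erythroid (0.61, adjusted p = 0.759) and mesothelial markers (-0.05, or 0.05 with no scaling, adjusted p = 0.759). Calls held in 10 of 26 other settings for Csf3r, 11 of 26 for Siglecf, 14 of 26 for Padi4 and 11 of 25 for Mmp8, and normexp ended those of Clec9a (0.22) and Siglech (0.21) and gave -2.02 for Mmp8. Quantile normalization ended that of Padi4 (0.41, adjusted p = 0.188). Of the genes that passed after PBS 58.3% were higher in Ifnar2-/- as analysed and 66.3% with no scaling. That share was 71.8% without Ifnar2-/- PBS replicate 1, and 41.9% of the 31 genes that passed with slide as a fixed block.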

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

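Of the tests in this part, those of slide, of shares drawn with no difference after PBS, of signalling left over through Ifnar2, of another constituent of the preparation, of resting interferon tone and of blood in the lavage were chosen after the result was seen. The results listed first were picked out because the effect of IFN-β differed between wild type and Ifnar2-/- by the interaction test or, for 9 genes, because it passed in opposite directions. In all 3247 genes differed. The median differences (Ifnar2-/- minus wild type) of lists that passed were -5.08 for antiviral genes, -4.77 for GTPases, -1.43 for MHC class I genes, -1.37 for monocyte markers, -0.88 for cell death genes, -0.68 for chemokines, -0.23 for pattern-recognition genes, 0.46 for chromosome 16 neighbours of Ifnar2, 0.47 for dendritic cell markers and 0.86 for the TREM and CD300 list. With an estimated correlation the antiviral, GTPase and cell death lists kept their calls (adjusted p = 0.00344, 0.00344 and 0.0141) and the other 7 lists did not (0.0706 to 0.588). Single genes were Rsad2 (-11.34), Ifit3 (-11.22), Cxcl11 (-10.71), Ifit2 (-10.48), Ifit1 (-10.46), Cxcl10 (-10.25), Il1r1 (5.74), Cxcl3 (5.60), Ngp (5.10), Sox7 (4.49), Ifnlr1 (4.25) and Gja1 (4.12).

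Genes that passed in both genotypes in opposite directions were 9. Higher in wild type and lower in Ifnar2-/- were Cmpk2 (8.63 and -1.20, difference -9.83), Mgst2 (0.89 and -1.23, difference -2.12) and Casp2 (0.88 and -0.57, difference -1.45). Lower in wild type and higher in Ifnar2-/- were Mmd (-2.28 and 0.94, difference 3.22), Creg2 (-0.88 and 1.51, difference 2.39), Cdc42ep2 (-0.54 and 1.27, difference 1.81), Lrrc75a (-0.53 and 0.93, difference 1.46), Stk40 (-0.45 and 0.84, difference 1.29) and Map2k3os (-0.60 and 0.57, difference 1.17). Over the other settings the difference held in all 25 for 8 of them and in 23 of 24 for Creg2, but the call in Ifnar2-/- held in 6 of 28 for Map2k3os, 7 for Cmpk2 and Mgst2, 8 for Casp2, 10 for Stk40, 14 for Lrrc75a, 20 for Mmd, 23 for Cdc42ep2 and 8 of 27 for Creg2. The call in wild type held in 11 of 26 for Stk40, 17 for Cdc42ep2, 18 for Lrrc75a, 22 for Mgst2 and 12 of 25 for Creg2. The replicate block ended the Ifnar2-/- calls of Casp2, Cmpk2, Map2k3os, Mgst2 and Stk40.

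For each comparison of 2 groups 1 of 10 splits of its 6 arrays, the real one, gave as many genes, and 10 splits are too few for a share under 0.05: the real and highest other counts were 7205 and 0 in wild type, 207 and 1 in Ifnar2-/-, and 892 and 0 after PBS. Among the 3 other Ifnar2-/- splits that part every same-numbered pair the highest count was 0. For the interaction 9 of 100 reassignments drawn from 200 gave at least the real 3247, the highest other giving 6638. In the 8 others the wild-type arrays kept their own groups. The wild-type response then stays in the difference, so these reassignments cannot test whether chance makes it. With wild-type arrays mixed the highest count was 5, but mixing also puts the wild-type response into the spread. The reassignments therefore decide nothing about chance for the interaction. For the 143 genes that passed in the same direction in both genotypes 1 of 100 reassignments, the real one, gave as many and the highest other gave 9. The 88 with wild-type arrays mixed shared 0 genes, which leaves 20 assignments of the Ifnar2-/- arrays to compare, too few for a share under 0.05.

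Inflammatory genes rose in Ifnar2-/- after IFN-β, and 4 explanations were set against a response to IFN-β that does not need Ifnar2. RNA of incoming neutrophils as the whole cause was argued against, since with each array's neutrophil marker median as a covariate the list kept its call (adjusted p = 0.000302) and its median went from 1.33 to 1.40, while the chemokine median went from 1.98 to 1.53. The same covariate left 34 genes called in Ifnar2-/-, 31 of them among the 207. Slide was argued against by the balance of both groups over slides and by the list's medians within them, 1.33 on slide 2 and 1.31 on slide 3. Signalling left over through Ifnar2 in the wild-type proportion was argued against too, since the mean change of antiviral genes in Ifnar2-/- was -0.0786 with an upper 95% limit of 0.214, where 85.5% of the wild-type inflammatory mean was kept and 85.5% of the antiviral mean would be 4.79. Another constituent of the injected preparation stays open, because 0 groups received the preparation without active interferon. A response to IFN-β that does not need Ifnar2 therefore stays a hypothesis, which these groups cannot tell apart from such a constituent.

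Levels after PBS differed between the genotypes for 892 genes, and genetic background, slide and a resting interferon signal were weighed. With the interferon lists left out, 82 pairs of neighbouring genes both passed against a median of 34 in 10000 random placements (0 reached 82, permutation p = 1e-04, the smallest they can give), but as many top genes of the wild-type response also gave 82 pairs and those of the Ifnar2-/- response 51, so background stays open. Slide as the whole cause of these differences was argued against, since with slide as a block they had a median of 0.942 times their size without it (quartiles 0.757 and 1.10) and kept their sign in 891 genes; 31 genes passed in that fit because the SE grew to a median of 1.98 times, no slide holding both PBS groups, so slide stays open for single genes such as the 73 whose difference was under 0.5 times its size. The lower antiviral genes (adjusted p = 3.02e-05) are consistent with loss of a resting interferon signal through Ifnar2, although slide as a block ended that call (median -0.91 against -1.07, adjusted p = 0.0638). Of the 372 lower genes 57 (15.3%) were at least 4-fold higher after IFN-β in wild type, and of the 520 higher genes 33 (6.35%), where 100 draws with no difference after PBS and the same wild-type PBS arrays in both comparisons gave medians of 3.49% (95% range 1.88% to 5.11%) and 5.96% (4.32% to 8.37%).

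Neutrophil markers differed between arrays of a group: the array medians were 1.71, -0.52 and -1.42 after PBS in wild type and 0.13, 1.18 and 2.76 after IFN-β in Ifnar2-/-, against -0.27 to -0.15 in wild type after IFN-β and -0.99 to -0.40 in Ifnar2-/- after PBS. For the wild-type PBS arrays slide was argued against, since all lay on slide 1 and their medians ranged over 3.12. For Ifnar2-/- after IFN-β slide stays open, since the arrays of slide 3 lay on average 1.84 above the 1 array of slide 2 and differed by 1.58, while after PBS the difference between these slides was -0.07. Blood in the lavage stays open, with r = 0.276 between erythroid and neutrophil medians as deviations from group means over 12 arrays (exact permutation p = 0.427; Spearman's rho = 0.531, p = 0.109; r = 0.285 without the 2 arrays farthest out). A difference between mice in recruited neutrophils may also be the cause and was not tested.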

How the results depend on the processing

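The settings with no scaling between arrays, with both arrays of high neutrophil signal left out and with the 6 Ifnar2-/- arrays fitted under a block were chosen after the result was seen. By the directional set tests, under every setting run, the antiviral list kept its call in wild type (adjusted p 3.36e-11 to 7.61e-06 by fry) and in the comparison of responses (1.17e-09 to 1.50e-06) and did not pass in Ifnar2-/- (0.509 to 0.981; the mixed test gave 0.00155), and the inflammatory list kept its call in Ifnar2-/- (7.91e-06 to 0.0292). The cause of the changes below was not tested, except where fewer arrays, fewer genes or a stricter threshold make them. Signal over background limits 284 of the genes called in wild type, 15 in Ifnar2-/- and 53 after PBS, for which a group was not well above it.

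Genes changed in wild type were 4427 with slide as a fixed block and 3264 at 2-fold or more. Genes changed in Ifnar2-/- were 331 with normexp, 68 without the filter on dim probes, 118 with slide as a fixed block, 13 from the arrays of the groups alone, 359 with a trend and robust variance, 125 without both arrays of high neutrophil signal, 133 at 2-fold, 32 at an adjusted p under 0.01, and 32 to 293 with an array left out. With the replicate number as a block they were 138 over all 12 arrays; in the 6 arrays alone that block gave 0 by limma (2800 at an unadjusted p under 0.05) and slide as a block gave 2. The block over 12 arrays ended the Ifnar2-/- calls of Ptgs2, Slc7a11, Mgst2, Cmpk2, Tlr2, Cd14, Mt2 and Itgax and of no other named gene of that comparison. Genes whose responses differed were 1921 with slide as a fixed block, 4980 with array weights, 2081 at 2-fold and 1692 at 0.01. After PBS they were 31 with slide as a fixed block, 1858 with array weights, 578 at 2-fold, 367 at 0.01 and 437 to 1255 with an array left out, the last without Ifnar2-/- IFN-β replicate 3. Genes changed in both genotypes were 227 with normexp, 50 without the filter, 72 with slide as a fixed block, 8 from the groups alone, 242 with a trend, 78 at 2-fold, 26 at 0.01 and 24 to 208 with an array left out. Without the filter the responses correlated at 0.237.

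The chemokine list in Ifnar2-/- lost its call in the 6 arrays with a replicate block (median 1.98, 0.0953, range over settings 2.05e-06 to 0.0953) and had 1.14 within slide 2; antiviral genes there had 0.19. In the comparison of responses chemokines lost their call with probes above background on all 12 arrays (-0.11, 0.0894) and with an estimated correlation (-0.68, 0.192). The inflammatory list passed there with the filter on all 12 arrays (-0.20, 0.041), slide as a fixed block (-0.24, 0.048) and array weights (-0.20, 0.018), with medians from -0.29 to -0.11 when an array was left out, and passed without Ifnar2-/- IFN-β replicate 2 (0.0072); over all settings p ran from 0.00722 to 0.782. After PBS the antiviral list lost its call with slide as a fixed block (-0.91, 0.0638, the highest of a range from 4.83e-06). Ifnar2 in wild type, at 0.006 and not called as analysed, was lower under quantile normalization (-0.40, adjusted p = 0.0277). Itsn1 turned its sign as the mean of its probes, in wild type (0.64, adjusted p = 0.0191) and, with no call, between the responses (-0.48, adjusted p = 0.262).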

Other observations

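The gene pairs in this part were chosen after the result was seen. After PBS, some neighbouring genes of a family differed together between Ifnar2-/- and wild type. Of the Klk1b kallikreins, serine proteases encoded side by side on chromosome 7, Klk1b24 (3.60), Klk1b21 (2.55), Klk1b4 (2.51), Klk1b27 (2.49), Klk1b26 (2.46), Klk1b3 (2.22) and Klk1b5 (1.90) were all higher in Ifnar2-/-, as was their neighbour Klk1 (2.23). These genes are near-identical copies, so their probes are not independent. The acute-phase genes Orm3 (-3.42), Orm1 (-2.91) and Orm2 (-2.83) on chromosome 4 were lower, as were the lectin receptor genes Clec12b (-3.69) and Clec1b (-2.65) on chromosome 6. Neighbours also went in opposite directions: on chromosome 17 H2-Eb2 was higher (3.51) beside H2-Ea, which was lower, and on chromosome 6 the lectin-like NK receptor gene Klra3 was higher (1.93) beside Klra1 (-5.41). Each of these genes passed limma's test over all genes, but no slide held both PBS groups. Genetic background cannot be told apart from loss of Ifnar2 for them either.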
